A study of Mus musculus with 32 samples.

How the data were processed

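RNA was taken from the left ventricle of 32 C57Bl6 mice, extracted with TRIzol, amplified from an oligo(dT) primer, labelled with biotin and put on 1 Affymetrix mouse 430 2.0 array per mouse, per the labels' protocols. Each group of sex, genotype and surgery had 4 individual mice, per the labels. The labels give the age as 10 weeks without saying whether at surgery or at the end, and state a TAC duration of 9 weeks for the 8 knockout TAC mice and none for the 8 wild-type TAC mice. The deposited values are linear signal intensity per probe set, made with MAS5 5.0 per the submitters' processing notes. No other step by the authors, no array batch, scan date or genome build is given in the sources used here. The 2% trimmed mean was 500 on every array, so the table counted as already normalized and was used as deposited.

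The table held 45101 probe sets, 64 of them array controls that stayed out of all tests. In the platform annotation used, 34957 had 1 gene symbol, 920 had several and 9160 had none named here. The named ones stood for 18201 genes. RefSeq gene tables of mouse assembly GRCm38.p6 served only for names and for which genes are neighbours. A gene was represented by its probe set with the highest mean log2 value over all arrays. Values were taken as log2(signal + 32), so fold changes are on the log2(value + pseudocount) scale and understate the change of low genes. Genes with a mean at or above the median of the non-control probe sets (7.11 on the log2 scale, a signal of 106.1) were tested, which left 11016. Panel genes below that level stayed out of the limma tests. They were Esr2, compared between genotypes by a separate permutation test, and Esr1 and Gper1, which were not tested. Group mean signals ran from 83.48 to 131.4 for Esr1 and from 83.95 to 113.2 for Gper1.

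Each of 14 comparisons was a contrast of the 8 group means in 1 limma fit (limma 3.58.1 in R 4.3.3; lmFit, contrasts.fit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment within the comparison, a threshold of 0.05 and no fold minimum. The rule for scaling, the filter, the tests, the rule for named genes and 30 gene lists were fixed before the data were examined. Of their 787 entries, 711 were named on the array, and the 25 lists with 5 or more tested members were tested with camera (preset correlation of 0.01), adjusted over the lists of a comparison. An estimated correlation was the alternative. For each list the members past 0.05 were counted over all genes and adjusted over the list alone. Mean log2 values of 4 lists per mouse and the array controls were compared by exact permutation of 4 against 4 mice. Genes to be named were fixed by rule: the 8 largest rises and 8 largest falls among genes past the threshold with a symbol that is not a clone name, up to 3 per list with the smallest p, and a panel of 26 genes, 23 of which were named on the array. Where no gene passed, the 3 with the smallest p were named. Probe sets of the same gene with an unadjusted p under 0.05 and the opposite sign were counted as disagreeing.

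Other settings were quantile normalization, centring on the array median, pseudocounts of 1 and 128, no filter and a stricter filter on low values, every probe set alone, the mean of a gene's probe sets, the replicate number as a block, array weights, eBayes without a trend and robust, only the groups compared, a 3-prime over 5-prime covariate, a fold minimum and leaving out each array in turn. After seeing the data, 4 more were added: the fetal list without its atrial markers, leaving out the 4 arrays farthest from their group mean along the first principal component of the within-group residuals, the pyruvate carboxylase control's 3-prime over 5-prime difference as a covariate, and array weights by the gene-by-gene method. The last was added because the default estimate of array weights stopped before it converged and gave male knockout sham replicate 1 a weight of 17.5.

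The fit was tested on simulated data with 200 of 11016 genes changed. For TAC against sham in wild-type males, 26.9%, 88.1% and 98.5% of genes changed by 0.5, 1 and 2 (log2) were recovered, with 5 false calls. For the sex difference in the response of wild-type mice, 10.4%, 62.7% and 93.9% were recovered, with 7 false calls. The simulated noise was independent between genes, with 1 spread per gene in all groups. The real arrays shared differences across genes (a first within-group component with 30.4% of the variance) and differed in spread between groups. These rates and false calls therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9. Probe sets with several symbols or none were left out of the gene-level tests, and some list genes were not analysed here because no probe set named them alone.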

Results

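Left ventricular RNA of 32 mice was measured on Affymetrix mouse 430 2.0 arrays, 1 array per mouse. The mice fell into 8 groups of 4 by sex, by genotype (wild type, or labelled as knockout of oestrogen receptor beta, the product of Esr2) and by surgery. Transverse aortic constriction (TAC), a narrowing of the aorta that loads the left ventricle with pressure, was set against a sham operation. Every array had a 2% trimmed mean signal of 500, and the median signal ran from 101.5 to 127.7. Arrays of the same group correlated at 0.914 to 0.988 across genes, which are not independent replicates. Values below are log2 changes ± SE from limma, with 4 mice per group, unless stated otherwise. The number of arrays limits their precision. In the main fit the SEs and limma p-values rest on 1 spread between mice per gene, shared by all 8 groups. They do not measure the spread within the stratum named, and the groups differed in spread. Camera p-values with the preset correlation use a fixed correlation between the genes of a list, which was not estimated from these mice.

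The targeted gene was examined first. The Esr2 probe set had a signal of 113 ± 53.8 (SD, n = 16) in the mice labelled knockout and 18.3 ± 15.6 (SD, n = 16) in wild-type mice. The log2 difference was 1.48. The signal was higher in the mice labelled knockout in a two-sided permutation test within sex and surgery (p = 1e-05, the smallest that 100000 permutations can give), and 12 of the 16 lay above the highest wild-type mouse. Where the probe set lies relative to the disrupted part of the gene is not given in the sources used here, so this signal checks no label, and the genotype is used as labelled. Its mean lay below the level at which genes were tested. Xist, which is transcribed from the inactive X chromosome, and the Y-linked genes Eif2s3y, Kdm5d and Uty separated all 16 females from all 16 males: Xist lay between 12.25 and 12.98 (log2) in females and between 6.51 and 7.68 in males.

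**Figure D1:**
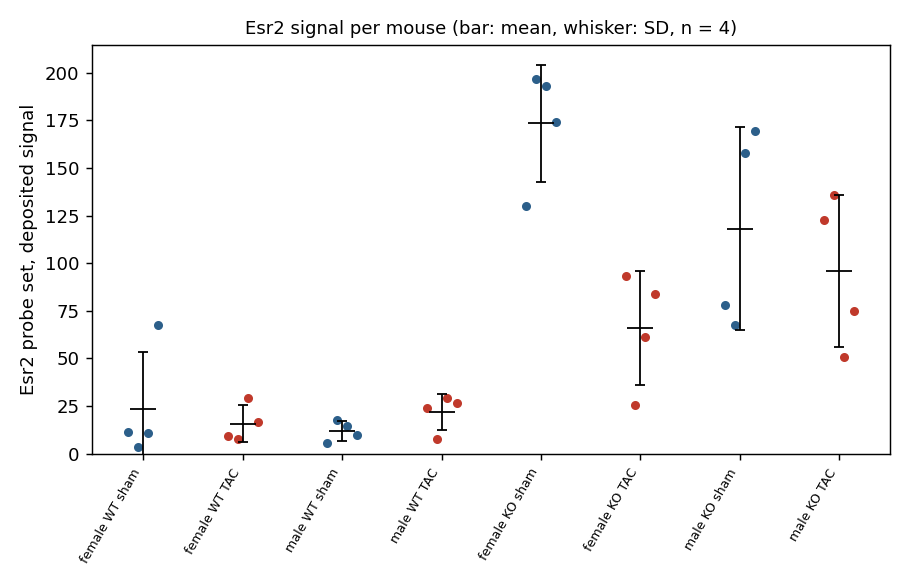
Deposited signal of the Esr2 probe set (vertical axis, linear) in each of the 32 mice by group, with sham in blue and TAC in red; bars are group means and whiskers SDs (n = 4). The 16 mice labelled knockout lay between 25.8 and 196.8, and the 16 wild-type mice between 3.6 and 67.7.

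TAC against sham over the mean of the 4 sex and genotype strata asked which genes changed with pressure overload on average. A large change in 1 stratum can carry such a mean, so a call does not show a change in every stratum. Myh7, the slow myosin heavy chain of the fetal ventricle, rose by 3.28 ± 0.12, a 9.74-fold change. The other genes among the 8 largest rises were Mfap4 (4.06 ± 0.29), Comp (3.43 ± 0.31), Ltbp2 (3.27 ± 0.26), Cilp (3.12 ± 0.19), Thbs4 (2.82 ± 0.20) and Postn (2.67 ± 0.27), which encode proteins of the extracellular matrix, and the acute-phase gene Serpina3n (2.90 ± 0.41). Among the largest falls were Cenpf (-2.14 ± 0.13), Gpr22 (-1.78 ± 0.18), Retnla (-1.77 ± 0.16), the acyl-CoA thioesterase Acot1 (-1.75 ± 0.25), Ano10 (-1.66 ± 0.10), Ces1d (-1.64 ± 0.18) and the potassium channel gene Kcnj3 (-1.50 ± 0.19). In limma, 4540 of 11016 genes passed a Benjamini-Hochberg adjusted p of 0.05, 2584 higher and 1956 lower. Of these, 2288 higher and 1785 lower genes had the same sign in all 4 strata. Genes that passed in each of the 4 strata taken alone numbered 133 higher and 53 lower. With each array centred on its median the split was 2042 higher and 2668 lower, with the Gapdh 3-prime over 5-prime difference as a covariate 2042 genes passed, and 1141 passed with an absolute log2 change of at least 0.5.

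The fetal and stress gene programme rose as a list: 22 of 27 members rose and 1 fell, and 22 rose and 1 fell when adjusted over the list alone. Nppa, the gene of atrial natriuretic peptide, rose by 2.13 ± 0.17, Acta1 (skeletal alpha-actin) by 2.30 ± 0.13, Nppb by 1.03 ± 0.17 and Ankrd1 by 0.69 ± 0.08. Nppb rose least in wild-type males, with group means of 13.98 in sham and 14.34 in TAC mice (log2). Atrial genes varied widely between mice of the same group: Myl7, the atrial myosin light chain gene, ran from 5.29 to 14.04 (log2) in wild-type female sham mice and from 5.85 to 12.35 in wild-type male TAC mice. In each of the 4 sham groups the mouse with the highest mean of the fetal list also had the most Myl7 and Sln. The fetal list itself includes atrial markers, which help set its mean, so this coincidence is partly built in and is no separate evidence. Without the members that are also atrial markers, Nppa among them, the mean of the other 24 fetal genes was higher after TAC by 1.03, 0.885, 1.05 and 1.26 in wild-type females, wild-type males, knockout females and knockout males (exact permutation p = 0.0286, adjusted p = 0.0416, in each), in a comparison added after the data were seen. The alpha myosin heavy chain gene Myh6 did not pass (-0.16 ± 0.08, adjusted p = 0.0952). It passed without wild-type female TAC replicate 1 (-0.22, adjusted p = 0.00105) and without knockout male TAC replicate 1 (-0.18, adjusted p = 0.0494), so no lack of change is read from it. Its probe set gave the highest signal of the array on at least 4 sham arrays, and whether the range of the scanner was reached is not given in the sources used here. The same is open for Nppa and Acta1 after TAC. In knockout male TAC mice they reached 48844.6 and 47332.2, where the highest signals per array were 43898.1 to 58995.9. If the range was reached, their rises are understated. The extracellular matrix and fibrosis list had 53 of 60 members higher and 2 lower, the same numbers when adjusted over the list alone, with a median log2 change of 1.08. Col8a1 rose by 2.35 ± 0.18, Timp1, an inhibitor of matrix metalloproteinases, by 2.13 ± 0.29, Col1a1 by 1.78 ± 0.19 and Col3a1 by 0.98 ± 0.12. Timp1 did not pass in wild-type females, wild-type males or knockout females taken alone. Its signal ran from 442 to 9240.5 in knockout male TAC mice. In the TGF-beta signalling list 19 of 28 rose and 3 fell (21 and 3 adjusted over the list alone), with Ccn2 at 2.31 ± 0.19, Tgfb2 at 1.34 ± 0.15 and Tgfb3 at 1.24 ± 0.10. By camera the fetal list passed with the preset correlation (adjusted p = 4.77e-15) and with an estimated one (adjusted p = 0.0253 with an estimated correlation). The matrix and TGF-beta lists passed only with the preset correlation (adjusted p = 0.0706 each with an estimated correlation).

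In the oxidative phosphorylation list 59 of 73 members fell and 0 rose (63 fell adjusted over the list alone), with a median of -0.24; Sdha fell by 0.51 ± 0.05 and Ndufa5 by 0.46 ± 0.05. Of 39 genes of fatty acid uptake and oxidation 28 fell and 0 rose (30 fell adjusted over the list alone), Decr1 by 0.70 ± 0.08, Ech1 by 0.69 ± 0.08 and Etfb by 0.60 ± 0.07. Of 22 genes of the TCA cycle and pyruvate entry 16 fell and 0 rose, the same when adjusted over the list alone, Idh3a by 0.51 ± 0.06. The coactivator gene Ppargc1a fell by 0.68 ± 0.10, while Pdk4 did not pass (0.05 ± 0.25, adjusted p = 0.88). Of 28 genes of calcium handling and ion channels 16 fell and 0 rose, also when adjusted over the list alone, among them Kcnd2 (-1.19 ± 0.12), Kcnv2 (-1.09 ± 0.09), Kcnj5 (-1.02 ± 0.11) and Atp2a2 (-0.22 ± 0.08). All 4 lists passed camera with the preset correlation. The ion handling list passed with an estimated one too (adjusted p = 0.0260 with an estimated correlation), unlike fatty acid oxidation (adjusted p = 0.0979 with an estimated correlation), the TCA cycle (adjusted p = 0.0706 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.210 with an estimated correlation).

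Of the marker lists of other cells, those of macrophages and fibroblasts passed with the preset correlation and none with an estimated one. Of 23 macrophage and monocyte genes 18 rose and 0 fell, with a median of 0.51; C1qc rose by 0.92 ± 0.15 and Tyrobp by 0.69 ± 0.12. Of 19 fibroblast genes 11 rose and 1 fell. Of 18 cell cycle genes, which mark no cell type, 14 rose and 0 fell, and these 3 counts were the same when adjusted over the list alone. Of 20 immediate early genes 15 rose and 0 fell (16 adjusted over the list alone), with Egr2 at 1.51 ± 0.18, and of 23 interferon response genes 7 rose and 1 fell, the same when adjusted over the list alone. These 5 lists passed with the preset correlation and not with an estimated one (adjusted p = 0.359, 0.3, 0.3, 0.21 and 0.605 with an estimated correlation, in that order). The apoptosis lists did not pass: of 30 pro-apoptotic genes 9 rose and 6 fell (adjusted p = 0.653), and of 19 anti-apoptotic genes 5 rose and 2 fell (adjusted p = 0.414). Bcl2 rose by 0.88 ± 0.11 and Bcl2l11 fell by 0.83 ± 0.09. The lists that did not pass had these members higher and lower: circadian clock 2 and 3 of 18, cytosolic ribosomal proteins 2 and 1 of 34, ER stress 5 and 5 of 23, glycolysis 4 and 5 of 19, atrial myocyte 5 and 2 of 11, endothelium 7 and 2 of 17, mesothelium 2 and 0 of 7, pericyte and smooth muscle 6 and 7 of 13, Schwann cell 3 and 1 of 6, sarcomere 4 and 4 of 25, and sex-chromosome genes 0 and 3 of 7. Adjusted over the list alone these counts were the same except for ribosomal proteins (0 and 0) and glycolysis (5 and 5). Adipocyte, erythroid, neutrophil, skeletal muscle and lymphocyte lists had under 5 tested members and no list test. For Mbp, a myelin gene that rose by 0.38 ± 0.11, 5 of 7 other probe sets went the other way. The beta-actin control's 3-prime over 5-prime log2 difference was lower after TAC in each stratum, by -0.31 in wild-type females, -0.41 in wild-type males, -0.41 in knockout females and -0.36 in knockout males (exact permutation p = 0.0286 each, unadjusted). The Gapdh control, the one for which a test had been planned, had differences of 0.065, 0.092, 0.056 and 0.069 in the same order (exact permutation p = 0.0857, 0.0571, 0.0286 and 0.143, unadjusted); the beta-actin test was added later.

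**Figure D2:**
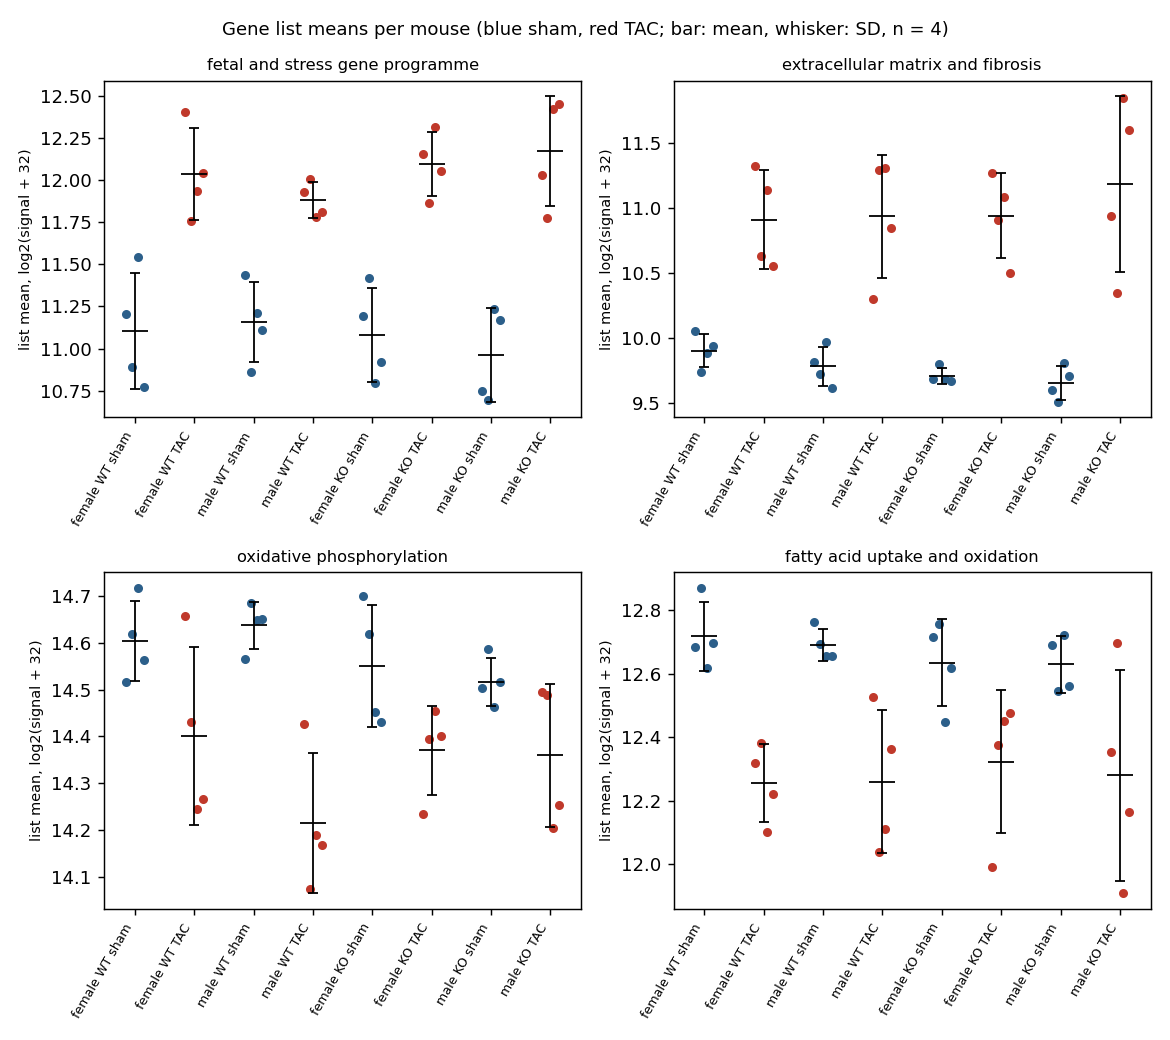
Mean log2(signal + 32) over the tested members of 4 gene lists (vertical axes) in each of the 32 mice by group, with sham in blue and TAC in red; bars are group means and whiskers SDs (n = 4). For the fetal and matrix lists the TAC means lay above the sham means in every stratum, by 0.73 to 1.21 and by 1.01 to 1.53.

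The same lists were averaged per mouse and compared within each stratum by a two-sided exact permutation test, whose smallest p with 4 mice against 4 is 0.0286; 16 comparisons were adjusted together. The fetal and stress list was higher after TAC by 0.93 in wild-type females, 0.73 in wild-type males, 1.01 in knockout females and 1.21 in knockout males (exact p = 0.0286, adjusted p = 0.0416, in each). The matrix list was higher by 1.01, 1.16, 1.23 and 1.53 in the same order (exact p = 0.0286, adjusted p = 0.0416, in each). Oxidative phosphorylation passed in wild-type males (-0.42, exact p = 0.0286, adjusted p = 0.0416), with -0.20 in wild-type females (exact p = 0.143), -0.18 in knockout females (exact p = 0.0857) and -0.16 in knockout males (exact p = 0.143). Fatty acid oxidation passed in wild-type females (-0.46) and males (-0.43; exact p = 0.0286, adjusted p = 0.0416, in both) and not in knockout females (-0.31, exact p = 0.0857) or males (-0.35, exact p = 0.114). These calls rest on 4 mice per group: without any 1 of the 4 sham arrays of wild-type males the smallest adjusted p over the 16 comparisons was 0.0571 and none passed. The changes in wild-type males moved little then: matrix was 1.10 to 1.22, oxidative phosphorylation -0.45 to -0.41 and the fetal list 0.63 to 0.82. The other strata were unchanged. These lost calls thus reflect the coarse steps of the exact p and the joint adjustment, and say little about stability. The fetal call in wild-type females also ended without TAC replicate 1, 3 or 4 of that stratum (0.81, 0.96 and 0.93), and the matrix call in knockout males without sham replicate 1, 2, 3 or 4 of that stratum (1.51, 1.48, 1.58 and 1.55). Oxidative phosphorylation passed in wild-type females without TAC replicate 1 (-0.29), and fatty acid oxidation in knockout females without sham replicate 3 (-0.37) and in knockout males without TAC replicate 2 (-0.49). With quantile normalization oxidative phosphorylation passed in all 4 strata, and the change in wild-type males shrank from -0.42 to -0.17, beside -0.12 in wild-type females, -0.105 in knockout females and -0.13 in knockout males (adjusted p = 0.0305 each). Fatty acid oxidation then passed in wild-type females (-0.43), wild-type males (-0.34) and knockout females (-0.29), and not in knockout males (-0.35, adjusted p = 0.0857).

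In wild-type females Myh7 rose by 3.69 ± 0.24 (12.9-fold), Serpina3n by 3.21 ± 0.82, Comp by 3.20 ± 0.62, Ltbp2 by 2.83 ± 0.52, Mfap4 by 2.79 ± 0.58 and Dio2, which encodes the enzyme that activates thyroid hormone, by 2.70 ± 0.44. Cenpf fell by 2.14 ± 0.26, Acot1 by 2.12 ± 0.50, Retnla by 2.04 ± 0.31 and Ano10 by 1.61 ± 0.21. Nppa rose by 2.10 ± 0.34 and Nppb by 1.29 ± 0.34. The call of Nppb ended without TAC replicate 1 (1.03) or 3 (1.35) or sham replicate 2 (1.09), 3 (1.20) or 4 (1.35). That of Serpina3n ended without TAC replicate 1 (2.95) or 3 (2.64) or any of the 4 sham replicates (3.20 to 3.22). That of Acot1 ended without TAC replicate 1 (-2.08) or 3 (-1.94) or sham replicate 2 (-2.03). TAC replicate 1 had a highest signal of 95436.7, against 42893.8 to 54306.7 on the other 3 TAC arrays. On it Myh6, Nppa, Acta1, Ankrd1 and Atp2a2 had signals of 95059.1, 83417.5, 82120.8, 71490.5 and 70159.5. Of the lists, 15 of 27 fetal genes rose, 23 of 60 matrix genes rose, 10 of 39 fatty acid oxidation genes fell and 2 of 73 oxidative phosphorylation genes fell (18, 40, 19 and 2 adjusted over the list alone, where 1 fetal gene also fell). Of the lists tested, only the fetal list passed with an estimated correlation (adjusted p = 0.0032). In limma 226 genes were higher and 135 lower, against 188 and 179 with arrays centred on their medians. The count of 361 became 687 with only these 8 arrays in the fit, 824 with gene-by-gene array weights and 836 with the default weights, whose estimate stopped before it converged. It fell to 158 and 232 with the Gapdh and pyruvate carboxylase covariates, and to 120 without TAC replicate 1, 134 without TAC replicate 3, 176 without sham replicate 2, 218 without sham replicate 4 and 232 without sham replicate 3.

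In wild-type males Mfap4 rose by 4.25 ± 0.58 (19.1-fold), Myh7 by 3.20 ± 0.24, Cilp by 3.00 ± 0.37, Ltbp2 by 2.72 ± 0.52 and Pamr1 by 2.37 ± 0.40. Cenpf (-2.11 ± 0.26), Acot1 (-2.02 ± 0.50), Retnla (-1.65 ± 0.31) and the proenkephalin gene Penk (-1.64 ± 0.35) fell. The call of Acot1 ended without TAC replicate 2 (-1.70) or 3 (-1.92). Of 73 oxidative phosphorylation genes 44 fell and 0 rose (68 fell adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0422 with an estimated correlation); Atp5j fell by 0.61 ± 0.09 and Ndufa5 by 0.66 ± 0.11. With quantile normalization that median was -0.15. Other lists moved down with it. Sarcomere and Z-disc had a median of -0.33, with 4 of 25 members above 0 (1 higher and 2 lower, 1 and 5 adjusted over the list alone; preset adjusted p = 6e-05, adjusted p = 0.263 with an estimated correlation). Ribosomal proteins had a median of -0.12, with 6 of 34 above 0 (0 higher and 0 lower, also when adjusted over the list alone; preset adjusted p = 0.00148, adjusted p = 0.399 with an estimated correlation). With quantile normalization these 2 calls were lost, with medians of -0.001 and 0.05. In the TCA cycle list 11 of 22 fell (14 adjusted over the list alone), and in the matrix list 35 of 60 rose and 1 fell (48 and 1 adjusted over the list alone). For Gnao1 (1.37 ± 0.18) another probe set of the gene went the other way. In limma 342 genes were higher and 270 lower, against 280 and 362 with arrays centred on their medians. The count of 612 became 1271 with only these 8 arrays, 2943 with gene-by-gene array weights, 2990 with the default weights, whose estimate did not converge, 1239 without the 4 arrays farthest out along the first within-group component, and 189 with the Gapdh covariate. It was 974 without TAC replicate 1, 189 without TAC replicate 2, 251 without TAC replicate 3, 354 without sham replicate 2, 358 without sham replicate 4 and 399 without sham replicate 3.

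In females labelled knockout Mfap4 rose by 4.5 ± 0.58 (22.6-fold), Ltbp2 by 3.74 ± 0.52, Comp by 3.59 ± 0.62, Cilp by 3.30 ± 0.37 and Myh7 by 3.08 ± 0.24. Cenpf fell by 2.20 ± 0.26, Ano10 by 1.87 ± 0.21, Gpr22 by 1.68 ± 0.35 and Lgals4 by 1.45 ± 0.32. Of 60 matrix genes 34 rose and 0 fell, of 27 fetal genes 15 rose and 0 fell, and of 73 oxidative phosphorylation genes 2 fell and 0 rose (42, 18 and 1 adjusted over the list alone). The fetal list passed with an estimated correlation (adjusted p = 0.00616), and the matrix list did not (adjusted p = 0.0710 with an estimated correlation). In limma 413 genes were higher and 202 lower, and 3 of the 35 divisions of these 8 mice, the real one included, gave as many genes, with up to 1833 in another division. Of the 413 higher genes 377 were also higher in knockout males (81 if independent) and 162 in wild-type females (8.47 if independent), strata that share no mice. Their calls do share 1 spread per gene in the fit, so independence is only a rough reference. With wild-type females 233 calls were shared in direction, against at most 117 in the other divisions. The count of 615 was 338 with only these 8 arrays, 1313 without the 4 outlying arrays, 1883 with gene-by-gene array weights and 3299 with the default weights, whose estimate did not converge. It was 311 without TAC replicate 3, 342 without sham replicate 3, 343 without sham replicate 4, 368 without TAC replicate 2 and 923 without TAC replicate 4.

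In males labelled knockout Mfap4 rose by 4.69 ± 0.58 (25.9-fold), Comp by 4.39 ± 0.62, Ltbp2 by 3.79 ± 0.52, Nmrk2, a nicotinamide riboside kinase gene, by 3.75 ± 0.69, and Cilp by 3.51 ± 0.37. Gpr22 (-2.63 ± 0.35), Kcnj3 (-2.13 ± 0.38), Cenpf (-2.11 ± 0.26), Ces1d (-2.10 ± 0.37) and Kcnd2 (-1.96 ± 0.25) fell. Of 60 matrix genes 51 rose and 2 fell, also when adjusted over the list alone. Of 27 fetal genes 20 rose, of 28 TGF-beta genes 18 rose and 1 fell, of 23 macrophage genes 11 rose, and of 73 oxidative phosphorylation genes 12 fell and 1 rose (21, 19 and 2, 13, and 7 and 1 adjusted over the list alone). No list passed with an estimated correlation (the fetal list had an adjusted p = 0.0824 with an estimated correlation). In limma 2161 genes were higher and 1425 lower, against 1718 and 1944 with arrays centred on their medians. The count of 3586 was 1157 with only these 8 arrays in the fit, below the 1271 of wild-type males in the same setting. It was 5236 with gene-by-gene array weights, 7031 with the default weights, whose estimate did not converge, 2102 with the Gapdh covariate, 2282 without sham replicate 1 and 2039 without sham replicate 2.

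**Figure D3:**
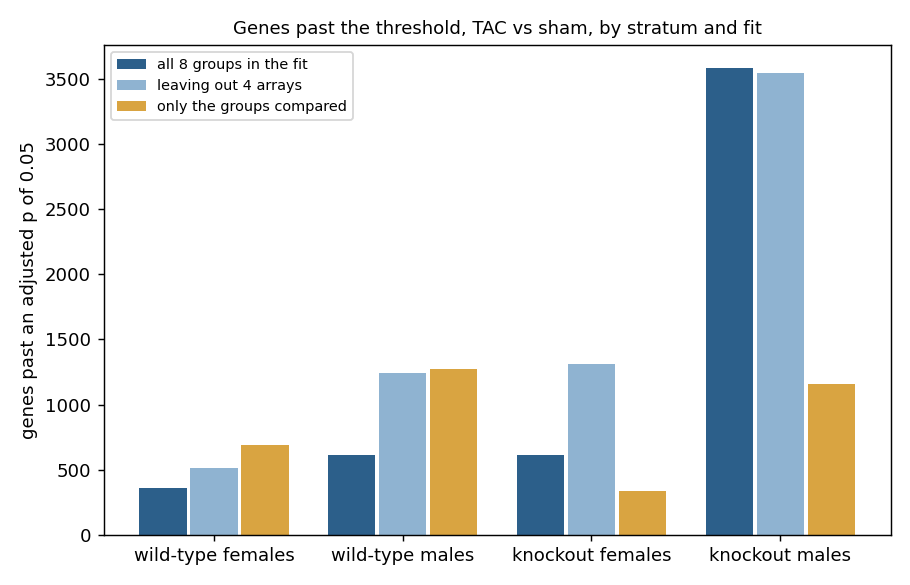
Number of genes past an adjusted p of 0.05 for TAC against sham (vertical axis) in the 4 strata, with all 8 groups in the fit, without 4 outlying arrays, and with only the 2 groups compared. The count in knockout males was 3586 with all groups in the fit and 1157 with only its own 8 arrays.

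The responses of the strata, which share no mice, were set against each other. Across the 11016 genes the log2 changes of wild-type females and males correlated at 0.758, those of knockout females and males at 0.788, those of the females of both genotypes at 0.748 and those of the males at 0.695; genes are not independent replicates. In all 4 strata 133 genes were higher and 53 lower. Over the genes past the threshold in the mean of the strata, the slope of male on female changes was 0.937 in wild type and 1.30 in knockout mice, and relabelling sex within genotype and surgery gave slopes as far from the median in 79 and 21 of 100 draws. The slope of knockout on wild-type changes was 0.981 in females and 1.29 in males, with 44 and 8 of 100 relabellings of genotype as far. Slopes of female on male changes were 0.823 in wild type and 0.618 in knockout mice. Those of wild-type on knockout changes were 0.782 in females and 0.557 in males. The ratios of response sizes were 1.07 and 1.45 (male over female) and 1.12 and 1.52 (knockout over wild type), in the same order. A slope under 1 is therefore no sign of a smaller response.

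The sex differences in the TAC response address the sex named in the title of the series. In wild-type mice no gene passed in limma; those with the smallest p were Gli2 (1.58 ± 0.34, adjusted p = 0.597), Tafa5 (1.13 ± 0.29) and Hps5 (0.85 ± 0.22). The stress genes Nppb (-0.92 ± 0.49), Acta1 (-0.76 ± 0.37) and Myh7 (-0.49 ± 0.34) and the collagen gene Col1a1 (0.70 ± 0.55) did not pass either. The median difference (male minus female response) was -0.22 for oxidative phosphorylation, -0.21 for sarcomere genes and -0.16 for ribosomal proteins, with 0 members past the threshold in each, also when adjusted over the list alone. Camera called 12 of 25 lists with the preset correlation and 0 with an estimated one (oxidative phosphorylation, adjusted p = 0.312 with an estimated correlation). With quantile normalization the oxidative phosphorylation median was -0.04 and the sarcomere call was lost. At an unadjusted p under 0.05 there were 198 genes in wild-type mice, 803 in knockout mice and 421 for the mean of genotypes, where 551 would be met by chance. In knockout mice the smallest p belonged to Pde1b (1.14 ± 0.24, adjusted p = 0.476), Itprip (0.79 ± 0.21) and Rad54l2 (0.94 ± 0.25), and for the mean of genotypes to Pde1b (0.64 ± 0.17, adjusted p = 0.900), Tbc1d10a (0.90 ± 0.25) and Tmem81 (0.61 ± 0.17), none past the threshold. The matrix list had a median of 0.31 in knockout mice (adjusted p = 0.959 with an estimated correlation) and 0.24 for the mean (adjusted p = 0.777 with an estimated correlation). With the default array weights 1, 526 and 57 genes passed for wild type, knockout and the mean. Those weights were from a fit that stopped before it converged, and gene-by-gene weights gave 1, 0 and 0. Without male wild-type sham replicate 1 the count in wild-type mice was 1, and without male knockout sham replicate 4 the count in knockout mice was 1.

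The genotype differences in the TAC response address the receptor named in the title. The labels state a TAC duration, 9 weeks, for the 8 knockout TAC mice and none for the 8 wild-type TAC mice, so a difference in duration would follow genotype exactly. In females no gene passed in limma, and Tafa5 (1.44 ± 0.29, adjusted p = 0.291), Pfn1 (0.74 ± 0.19) and Mef2c (-0.76 ± 0.20) had the smallest p. In males no gene passed; Fbxl6 (1.05 ± 0.21) and Rad9a (1.40 ± 0.27) had an adjusted p of 0.124 and Marchf10 (1.93 ± 0.41) of 0.136, and Kcnd2 was at -1.17 ± 0.35 (adjusted p = 0.245). For the mean of sexes Fbxl6 (0.79 ± 0.15), Mef2c (-0.72 ± 0.14), a cardiac transcription factor gene, and Pfn1 (0.75 ± 0.14), which encodes profilin, missed the threshold narrowly (adjusted p = 0.0505 each). In males the matrix list had a median difference of 0.37 (adjusted p = 0.899 with an estimated correlation), the fetal list of 0.35 (adjusted p = 0.656 with an estimated correlation) and oxidative phosphorylation of 0.29 (adjusted p = 0.585 with an estimated correlation), and 7 lists passed with the preset correlation. With quantile normalization none of these 7 passed, and only the TCA cycle list did (median -0.117, camera adjusted p = 0.0266). Over all genes no list member passed. Adjusted over the list alone, 3 of 19 glycolysis genes, 1 of 73 oxidative phosphorylation genes and 1 of 20 immediate early genes were higher in males, and 2 of 28 ion handling genes and 1 of 23 macrophage genes lower. For the mean of sexes 1 oxidative phosphorylation, 1 immediate early and 1 endothelial gene were higher and 1 ion handling gene lower by that adjustment, and for sex by genotype by TAC 1 Schwann cell and 1 macrophage gene lower. At an unadjusted p under 0.05 there were 314 genes in females, 1524 in males and 1219 for the mean. For sex by genotype by TAC no gene passed (369 at an unadjusted p under 0.05), and Cdh19 (-1.88 ± 0.49), Rad54l2 (1.36 ± 0.35) and Slc39a13 (1.21 ± 0.32) had the smallest p (adjusted p = 0.972). The count of 0 in males depended on single arrays and on their weights: it was 449 without male knockout sham replicate 4, 4 without male wild-type TAC replicate 1, 107 without the 4 outlying arrays, 2895 with gene-by-gene array weights and 4861 with the default weights. It was 1 without female wild-type sham replicate 2 and 1 without male wild-type sham replicate 4. For the mean of sexes it was 79 without male knockout sham replicate 4, 12 without female knockout TAC replicate 4, 9 without male wild-type TAC replicate 1, 8 and 4 without female knockout sham replicates 2 and 1, 3 without female knockout TAC 1, male knockout sham 3 or female wild-type sham 2, 2 without female wild-type TAC 1 or male wild-type sham 4, and 1 without male knockout TAC 2. It was 505 without the 4 outlying arrays, and 2792 and 4505 with gene-by-gene and default weights. In females it was 1 without knockout sham replicate 2, 1 without wild-type TAC replicate 4 and 4 with the default weights. The count for sex by genotype by TAC was 1 without male wild-type TAC replicate 1 and 8 with the default weights.

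Mice labelled knockout were compared with wild-type mice over the mean of the sex and surgery strata. Cog7, a subunit of a Golgi tethering complex, was higher by 0.84 ± 0.16, Ric8a by 0.75 ± 0.19 and Rps4l by 0.60 ± 0.13. Ctse, the cathepsin E gene, was lower (-0.99 ± 0.17), as were Gstm2 (-0.93 ± 0.24), Rab5b (-0.85 ± 0.18) and Timp3 (-0.80 ± 0.18). The glucose transporter gene Slc2a4 was lower (-0.46 ± 0.08) and Slc2a1 higher (0.46 ± 0.09), and Ryr2, the calcium release channel gene, was lower (-0.32 ± 0.06). Of 28 genes of calcium handling and ion channels 10 were lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.899 with an estimated correlation). Of 25 sarcomere genes 2 were lower, of 18 cell cycle genes 3 and of 20 immediate early genes 2 were higher (0, 4 and 2 adjusted over the list alone); these lists passed with the preset correlation only (adjusted p = 0.899 each with an estimated correlation). For Bcl2l11, Pdgfra and Slc25a20 other probe sets of the same gene went the other way. In limma 1002 genes were higher and 837 lower, 0 of them by 2-fold or more, and 162 by a log2 difference of at least 0.5, of which 30 were higher and 132 lower. The count of 1839 was 1208 without female knockout sham replicate 2, 2755 with gene-by-gene array weights, 3102 with the default weights, whose estimate did not converge, and 208 with the pyruvate carboxylase 3-prime over 5-prime difference as a covariate. That difference was 1.62 ± 0.22 (SD, n = 16) in the mice labelled knockout and 1.32 ± 0.31 (SD, n = 16) in wild-type mice.

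Males were compared with females over the mean of the genotype and surgery strata, and 17 genes passed, 7 higher and 10 lower. The sex-linked genes led: Xist was lower (-5.62 ± 0.10), Eif2s3y (5.48 ± 0.15) and Uty (3.56 ± 0.12) higher, and the X-linked Kdm6a (-0.87 ± 0.16), Eif2s3x (-0.54 ± 0.06) and Kdm5c (-0.54 ± 0.07) lower. Of the other genes, Car3, a carbonic anhydrase gene, was lower (-1.74 ± 0.34), as were Ptn (-0.75 ± 0.14) and Itm2a (-0.62 ± 0.09). Cxcl14, a chemokine gene, was higher (0.74 ± 0.14), as were Cpxm2 (0.68 ± 0.11) and Dpep1 (0.54 ± 0.09). Camera called 6 lists with the preset correlation and 0 with an estimated one (sex-chromosome genes, 2 higher and 5 lower of 7, also when adjusted over the list alone; adjusted p = 0.466 with an estimated correlation). The median of that list was -0.54 and its mean 0.16, of opposite sign. The count was 458 with the default array weights and 66 with gene-by-gene weights.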

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

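Of the tests below, the comparison of response sizes between male genotypes, the relabelling with weighted arrays, quantile normalization of the oxidative phosphorylation list, its comparison with sarcomere genes, the calls shared with wild-type mice in other divisions, and the settings without 4 arrays and with the pyruvate carboxylase covariate were chosen only after the result was seen.

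Of 208 groups of 4 arrays examined for the panel genes and list means, 12 held an array far from the other 3, where chance gives about 1 in 20. Male wild-type TAC replicate 1 had low Nppb (13.38, others 14.61 to 14.72 on the log2 scale), low Myh7 (14.41, others 14.85 to 14.91) and high Atp2a2 (15.22, others 14.96 to 14.99). Female wild-type TAC replicate 1 had high Nppb (15.82, others 14.76 to 14.85), and other abundant transcripts were high on it too: its highest signal was 95436.7 against 42893.8 to 54306.7 in the other 3 arrays, with Myh6 at 95059.1, Nppa at 83417.5 and Acta1 at 82120.8, so this is no feature of Nppb alone. Male wild-type TAC replicate 2 had low Ppargc1a (10.8, others 11.06 to 11.11) and low Kcnd2 (9.36, others 9.75 to 9.82). Kcnd2 was low in female knockout TAC replicate 3 (8.84), Col1a1 in female wild-type TAC replicate 2 (10.48), Tgfb2 in female wild-type sham replicate 1 (8.09), Myh7 in male wild-type sham replicate 1 (11.29) and Pdk4 in male knockout sham replicate 4 (11.81, others 13.65 to 13.97). The matrix list mean was high in female knockout sham replicate 2 (9.8, others 9.66 to 9.68).

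Gene lists whose TAC response differed between groups by camera with the preset correlation are given as median log2 differences; with an estimated correlation none passed (adjusted p = 0.305 to 0.959 with an estimated correlation). For males against females in wild type they were oxidative phosphorylation (-0.22), sarcomere (-0.21), ribosomal proteins (-0.16), the fetal programme (-0.14), TCA cycle (-0.11), TGF-beta signalling (0.08), matrix (0.11), cell cycle (0.21), Schwann cell (0.24), immediate early genes (0.33), mesothelium (0.46) and circadian clock (0.47). In knockout mice they were matrix (0.31) and cell cycle (0.34), and for the mean of genotypes ion handling (-0.16), TCA cycle (-0.11), oxidative phosphorylation (-0.10), TGF-beta signalling (0.21), matrix (0.24) and cell cycle (0.30). For knockout against wild type in males they were sex-chromosome genes (-0.30), ribosomal proteins (0.23), sarcomere (0.28), oxidative phosphorylation (0.29), the fetal programme (0.35), glycolysis (0.36) and matrix (0.37), none of which passed with quantile normalization. For the mean of sexes they were sex-chromosome genes (-0.26), ribosomal proteins (0.15), oxidative phosphorylation (0.16), TGF-beta signalling (0.18) and matrix (0.28). For sex by genotype by TAC they were oxidative phosphorylation (0.24), ribosomal proteins (0.25), glycolysis (0.30), sarcomere (0.33) and the fetal programme (0.43).

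Of 2966 tested probe sets without a single gene name (several symbols or none), 882 passed for TAC against sham over the mean of the strata, 312 higher and 570 lower.

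Other divisions of the same mice were tried for each count. Chance is unlikely for TAC against sham in wild-type females (361 genes, highest other of 35 divisions 2), wild-type males (612, highest other 12) and the mean of strata (4540, highest other of 100 relabellings 1220), and for knockout against wild type (1839, highest other 3). In each, 1 division, the real one, gave as many. That is the smallest share 35 or 100 divisions can give, and these tests were not adjusted for their number. In knockout males 1 of 35 divisions, the real one, gave 3586 genes, which makes chance unlikely by that count. Another division gave 3440, with sham replicate 4 in the place of TAC replicate 2, so the count alone hardly sets surgery apart from other differences among these arrays. Calls shared in direction with wild-type males numbered 466 in the real division, reached by 1 of 35, and at most 362 in the others. In knockout females (615) the count does not exclude chance, since 3 of 35 divisions gave as many, and 1833 in another, several times the real count, points to a structure of these arrays other than surgery. One side of that division held TAC replicates 1 and 4 and sham replicates 3 and 4. Their scores on the first within-group component were -5.9, -23.8, -22.5 and -21.1, and those of the other side were 11.1 to 27.7. Which genes passed makes chance less likely, in a test chosen after the count was seen and with a limit. For both sexes the wild-type calls came from the fit with the real grouping, whose shared spread includes the knockout mice. They were not recomputed for other divisions, which may favour the real one. With wild-type females 233 calls were shared in direction, reached by 1 of 35 divisions, against at most 117 in the others and 6 in the division with 1833. For males against females (17) 3 of 100 relabellings gave as many, and 1 gave 2573, which likewise points to a structure of the arrays. For the differences in response, relabellings with as many genes at an unadjusted p under 0.05 numbered 66 for sex in wild type (198 genes, highest other 744), 36 in knockout (803, 3864) and 47 for their mean (421, 2262), 53 for genotype in females (314, 1804), 10 in males (1524, 3805) and 12 for their mean (1219, 3041), and 50 for sex by genotype by TAC (369, 3117), of 100 each, so chance cannot be excluded.

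More genes passed for TAC in knockout males (3586) than in the other strata (at most 615). The tables argue against a single array, since the lowest count without 1 array of the stratum was 2039 (without sham replicate 2, and 2282 without sham replicate 1). Without the 4 outlying arrays it was 3545 and the others at most 1313. Those 4 included sham replicates 2 and 4 of this stratum, with opposite scores (-28.7 and 39.5). Leaving them out also changed the shared spread: wild-type females, who lost no array, went from 361 to 515 genes. That setting therefore cannot decide whether those arrays set the excess. With only the arrays of each stratum the count was 1157, below the 1271 of wild-type males, so a spread shared across 8 unlike groups may account for the excess. A larger response in knockout males stays open: 6 of 100 relabellings gave a ratio of response sizes as far from 1. With gene-by-gene weights 4 of 100 relabellings, the real one included, gave as many genes for the genotype difference in males as the real 2895, with up to 3496 in another and 42 of the others above 0, so that test is borderline.

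Many small differences separated mice labelled knockout from wild type (1839 genes, median absolute log2 difference 0.30, 162 at 0.5 or more, and 1208 genes without female knockout sham replicate 2). Of the 100 tested genes nearest to Esr2 on assembly GRCm38.p6, 18% passed against 16.7% of all. The exact 95% interval was 11 to 26.9%, which treats neighbouring genes as independent. The share and its upper bound lay below the share set beforehand for a linked chromosome segment. Calls were thus not concentrated among these neighbours. As 100 genes cannot hold 1839 calls, this could not test a segment as the whole source, nor its effects on genes elsewhere. Without the 4 outlying arrays 1587 genes passed, which argues against those as the whole source, though leaving them out also changed the shared spread. With the pyruvate carboxylase 3-prime over 5-prime covariate 11.2% of these genes (206) still passed, just above the 10% that bias as the cause was to leave at most, and the slopes on it within groups correlated at 0.60 with the genotype differences over these genes, as that cause would need; the median absolute difference went from 0.30 to 0.27, the covariate differs with genotype, and so 3-prime bias of the RNA and genotype cannot be told apart. No array batch is in the labels, and a batch that follows genotype stays open, as does an effect of the genotype itself.

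The TAC change of oxidative phosphorylation genes was lower in wild-type males than in wild-type females (median difference -0.22). A single mouse did not account for all of it, since without any 1 of 16 arrays the median stayed between -0.30 and -0.13. The latter was without female wild-type TAC replicate 1, so that array carried a large part. Its mean over the list was 14.658, against 14.245 to 14.431 in the other arrays of its group. Its highest signal, 95436.7, also stood apart from theirs. With quantile normalization it was -0.04, so differences between arrays in the distribution of values may account for most of it; the test against other genes in the list's range of level (-0.01) decided nothing, since that range held 9047 of 11016 genes, while genes matched on level had a median of -0.18. The sarcomere list differed by nearly as much (difference of the list means -0.02, exact permutation p = 0.728), though that p does not show the lists to be alike. Ribosomal proteins, not a myocyte list, had a median of -0.16, and with quantile normalization the sarcomere median was -0.005. The comparison therefore cannot tell a smaller share of myocyte RNA, which stays open, from differences in the distribution of values. Chance stays open too (difference of the list mean -0.22, exact permutation p = 0.117), as does an effect of sex.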

How the results depend on the processing

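Leaving out 4 arrays, the pyruvate carboxylase covariate, gene-by-gene weights and the fetal list without atrial markers were chosen after seeing the data; the other alternatives were planned. Counts that moved by over 1.5 times are given below; the cause was not tested unless stated. Slopes between strata moved by less than the spread of relabelled slopes under every alternative run for them.

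With array weights TAC against sham gave 836 genes in wild-type females, 2990 in wild-type males, 3299 in knockout females and 7031 in knockout males, the sex difference 1 in wild type, 526 in knockout and 57 for the mean, the genotype difference 4 in females, 4861 in males and 4505 for the mean, sex by genotype by TAC 8, knockout against wild type 3102 and male against female 458. These weights came from an estimate that stopped before it converged. Gene-by-gene weights gave 824, 2943, 1883 and 5236 for TAC in wild-type females, wild-type males, knockout females and knockout males, 2755 for knockout against wild type, 1 for sex in wild type, 2895 and 2792 for genotype in males and the mean, and 66 for male against female. With every probe set alone the counts were 1075 in knockout females, 6415 in knockout males, 8466 for the mean, 1 and 5 for genotype in males and the mean, 3910 for knockout against wild type and 39 for male against female; more features were tested. With the Gapdh covariate TAC gave 158 in wild-type females, 189 in wild-type males, 2102 in knockout males and 2042 for the mean, and with the pyruvate carboxylase covariate 232 in wild-type females and 208 for knockout against wild type. Without 4 arrays TAC gave 1239 in wild-type males and 1313 in knockout females, sex in wild type 1, genotype 1, 107 and 505 in females, males and the mean, and sex by genotype by TAC 1. With only the groups compared the 4 strata gave 687, 1271, 338 and 1157. A fold minimum of 0.5 gave 1141 for the mean and 162 for knockout against wild type, by its construction. The genotype difference for the mean of sexes was 3 with quantile normalization, 3 with centred arrays, 2 with the higher pseudocount, 2 with the mean of a gene's probe sets and 1 with the replicate block. After group means were removed, same-number arrays of different groups correlated at a mean r of 0.007 across genes over 112 pairs. Single pairs ran from -0.609 to 0.585, and arrays with different numbers had a mean of -0.002. The numbers therefore showed no pairing on average.

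The higher share of calls was 67.2% in knockout females and 54.7% with every probe set alone, 62.6% in wild-type females and 73.4% with the Gapdh covariate, and 54.5% for knockout against wild type and 40.5% with the mean of a gene's probe sets, 43.9% with every probe set alone and 18.5% with the fold minimum.

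Without each array in turn the counts ran from 120 to 444, 189 to 974, 311 to 923 and 2039 to 4921 in wild-type females, wild-type males, knockout females and knockout males, 4170 to 5223 for the mean, 0 to 1 for sex in wild type and in knockout, 0 to 0 for its mean, 0 to 1, 0 to 449 and 0 to 79 for genotype in females, males and the mean, 0 to 1 for sex by genotype by TAC, 1208 to 2511 for knockout against wild type and 15 to 21 for male against female. Lists called ran from 10 to 13, 15 to 17, 10 to 12 and 10 to 12 in the 4 strata, 11 to 13 for the mean, 5 to 15, 0 to 8 and 2 to 10 for sex in wild type, knockout and the mean, 0 to 7, 4 to 9 and 2 to 8 for genotype in females, males and the mean, 3 to 8 for sex by genotype by TAC, 2 to 7 for knockout against wild type and 4 to 9 for male against female. Slopes ran from 0.84 to 1.05 and 1.17 to 1.47 for males on females in wild type and knockout, and 0.883 to 1.10 and 1.07 to 1.48 for knockout on wild type in females and males. List means in wild-type females, wild-type males, knockout females and knockout males ran from 0.809 to 1.08, 0.628 to 0.819, 0.918 to 1.12 and 1.11 to 1.34 for the fetal programme, 0.871 to 1.13, 1.03 to 1.37, 1.12 to 1.38 and 1.31 to 1.81 for matrix, -0.29 to -0.152, -0.494 to -0.377, -0.22 to -0.13 and -0.203 to -0.106 for oxidative phosphorylation, and -0.504 to -0.411, -0.521 to -0.359, -0.373 to -0.2 and -0.489 to -0.226 for fatty acid oxidation. Calls on list means lost in strata whose arrays were all kept ended through the adjustment over 16 tests, since their values were unchanged.

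With an estimated correlation the lists called numbered 1, 7, 1 and 0 in the 4 strata, 2 for the mean and 0 for every other comparison. With quantile normalization they numbered 7 and 3 for sex in wild type and the mean, 1 for genotype in males and 0 for sex by genotype by TAC. For knockout against wild type 2 lists passed with a pseudocount of 1 and 2 with the stricter filter. For genotype in females 2 passed with no filter and 1 with the stricter filter, and for the mean 3 with the stricter filter and 3 without 4 arrays, while 1 passed for sex in knockout without 4 arrays. List means that came to pass with quantile normalization were oxidative phosphorylation in wild-type females (-0.121), knockout females (-0.105) and knockout males (-0.134) and fatty acid oxidation in knockout females (-0.293; -0.304 with the higher pseudocount). Oxidative phosphorylation in wild-type males still passed then, at -0.167 against -0.424.

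Results that turned direction were Laptm5 in knockout against wild type with the mean of its probe sets (-0.066) and, with quantile normalization, ribosomal proteins (0.054) and sarcomere (-0.001) for TAC in wild-type males, TCA cycle (0.007) and sarcomere (-0.005) for sex in wild type, TCA cycle (-0.117) and sarcomere (0.067) for genotype in males and TCA cycle (-0.082) for its mean; sarcomere for genotype in females turned without female wild-type TAC replicate 1 (0.114). For lists the direction is that of camera and the value is the median, which need not change sign with it. In the turned direction the TCA cycle passed camera for genotype in males (adjusted p = 0.0266) and its mean (adjusted p = 0.0214). Sarcomere for genotype in females passed too (adjusted p = 0.00939). The other lists turned with quantile normalization did not pass (adjusted p = 0.13 to 0.879). Over alternatives other than leaving out 1 array, named genes in a contrast kept their side of the threshold, and their direction where they passed, 10922 times. They lost the call 405 times and gained it 118 times, and lists did so 3256, 165 and 44 times. Here and for the turned results above, direction was compared only for results past the threshold in the main setting or the alternative. Genes with signals near the filter of 106.1 are the least certain, since signal over background limits what arrays show there.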

Other observations

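The component below was examined only after the data were seen. The first principal component of the differences between mice of the same group held 30.4% of their variance. Male knockout sham replicate 4 had a score of 39.5 on it, female knockout sham replicate 2 of 27.7, male wild-type TAC replicate 1 of 25.8 and male knockout sham replicate 2 of -28.7.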
